A study of Mus musculus with 5 samples.

How the data were processed

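Expression was measured with Affymetrix arrays in 5 mouse RNA samples, 1 array each, so every group holds a single sample. The sources used here give RNA extraction with a column kit and DNase treatment, and biotin labelling. Per the submitters' processing notes, the authors summarised the arrays with RMA in Affymetrix Expression Console. RMA corrects background, normalizes between arrays by quantiles and summarises probes into probe sets. The software version, the chip library files, the genome build and the annotation release are not given in the sources used here. The deposited values are signal intensities on a linear scale, as their range shows, from 5.80 to 11484 over the 5 arrays, and log2 was taken of them before any comparison. Array medians lay between 5.46 and 5.55 on the log2 scale. Arrays have no read depth. Scanner files were not used here, so neither detection above background nor saturation could be read for single probe sets, and the number of arrays limits the precision.

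The table has 41345 rows, 1 per probe set, of which 190 carry the identifiers of Affymetrix control probe sets. A table of the platform's annotation paired 23521 rows with exactly 1 gene symbol and 1814 with several, and gave no symbol for 16010. The 23521 rows covered 22180 symbols, and 22139 of these were found in a RefSeq gene table of the GRCm38 assembly that supplied gene biotypes.

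The comparisons, a size rule, 28 gene lists and the rule for naming genes were fixed before the data were examined. The rule named the 10 genes with the largest increases and the 10 with the largest decreases in each of 4 main comparisons, 3 and 3 in each of 3 secondary ones, and members of the lists. It could not be applied: tests on the control rows, gene families and repeated symbols, given first in the report, gave no sign that the level of a row follows its identifier, so that a row's identifier could not be relied on to say which gene its values belong to; whether this holds for every row stays open. No gene is therefore named as higher or lower. The planned reduction to 1 row per gene symbol was kept as an alternative, and the counts reported use all 41345 rows, a choice made after the data were seen. The control rows were not removed, since their identifiers could not be relied on to mark them. The planned spread of ribosomal protein and olfactory receptor genes, meant as a reference for differences between arrays, was void for the same reason.

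A row counted as different when its log2 signal differed by at least 1 between 2 arrays, a 2-fold difference, and the higher value was at or above that array's 50th percentile. With 1 array per group there is no test, no standard error and no p-value for any comparison between groups. Similarity of arrays was measured by Pearson and Spearman correlation across rows at or above the median in at least 1 array, and rows are not independent replicates. For rows past the 2-fold rule between the iMPC and MEF arrays, each remaining array was placed nearer to the iMPC or to the MEF value by the midpoint, with a 95% Wilson interval for the share that covers counting of rows only. Overlaps of counted rows were taken only between comparisons with no array in common and set beside the product of both counts divided by 41345. This reference is too low, since rows below the median in all arrays cannot pass the size rule. The median difference of each gene list was placed among 10000 random lists of the same size matched on mean signal in 20 bins. Permutation tests of row identity used 100000 permutations and were two-sided, with Benjamini-Hochberg adjustment over the 4 tests.

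The code of the size rule was checked on simulated data for the comparison of iMPC with MEF over 41345 rows. It found 200 of 200 rows shifted by known amounts, and no other row. Every shift exceeded the threshold, and the noise was smaller than the spread between the real arrays, so this outcome was set beforehand. It gives no rate of falsely counted rows for single arrays. On 22180 simulated symbols, a list of 42 sarcomere genes raised in the iMPC array lay at percentile 100.0 of the random lists. The rise was far larger than the largest list median in the data, 0.44. It therefore checks the code only and does not show that medians of that size would be found. Alternatives covered the row standing for a gene, the filter, the scaling, the threshold, an offset of 8 on the linear scale, identical rows counted once, and the way list medians were summarised. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.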

Results

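Gene expression was profiled in 5 mouse cell populations, from a series leading from fibroblasts to skeletal muscle progenitors and from a myoblast line outside that series. Mouse embryonic fibroblasts (MEFs) were the starting cells. A MEF population was collected on day 14 of induced expression of MyoD, the transcription factor that turns fibroblasts towards skeletal muscle. Another was collected on day 14 of MyoD induction together with small molecules abbreviated F/R, which are not spelled out in the sources used here. From general knowledge of the study they are taken to be forskolin, an activator of adenylate cyclase, and RepSox, an inhibitor of the TGF-β type I receptor. The fourth was an established line of induced muscle progenitor cells (iMPCs) at passage 6. The fifth was C2C12, a mouse myoblast line widely used as a model of muscle differentiation. The labels describe the MEF + MyoD sample as sorted for the fibroblast surface marker Thy1 at collection as well as at the start, whereas for the MEF + MyoD + F/R sample they mention only the sort of the starting cells. Each population was measured on 1 array, so no value below has a replicate error.

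The identifiers of the rows could not be relied on for gene identity: in tests on gene families, repeated symbols and control rows, signal did not follow the identifier. The 101 rows labelled as ribosomal protein genes, which every cell transcribes at a high level, had a mean log2 signal of 6.00 (SD over rows 2.17). The 1108 rows labelled as olfactory receptor genes, which are silent outside the nasal epithelium and a few other tissues, had a mean of 6.16 (SD over rows 2.12). The difference of -0.15 was no larger than random relabelling of these rows often gave (permutation test, two-sided p = 0.487), and the mean over all rows was 6.02. Protein-coding rows averaged 6.00 and long non-coding RNA rows 6.04. Over 1082 symbols represented by more than 1 row, the levels of the first pair of rows of a symbol were not positively correlated (across genes, Pearson r = -0.058, permutation p = 0.056; Spearman rho = -0.064; genes are not independent replicates).

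The control probe sets, which need no gene annotation, showed the same. Background probe sets of rising GC content normally brighten with GC count. Here the 23 background rows gave a Spearman rho of -0.18 (permutation p = 0.411) and a Pearson r of -0.173 (permutation p = 0.429). Over the 4 permutation tests of row identity the Benjamini-Hochberg adjusted p lay between 0.224 and 0.487. The row for a GC count of 5 stood at 10.77 and the row for a GC count of 25 at 4.23.

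Rows labelled with 6 genes that fibroblasts transcribe abundantly, chosen after the data were seen, were spread over the range of the MEF array. Of the 10 rows labelled Actb, Col1a1, Eef1a1, Gapdh, Sparc or Vim, 5 lay below the array's median of 5.48. The row labelled Actb, the cytoplasmic actin gene, read 4.66 in MEFs and the row labelled Sparc, a matrix protein gene, 3.18. The 3 rows labelled Gapdh, a glycolytic enzyme gene, read 10.58, 5.61 and 5.57. The row labelled Myod1 read 3.43 in MEFs, 3.43 in MEF + MyoD, 3.31 in MEF + MyoD + F/R, 3.48 in iMPCs and 3.71 in C2C12. It therefore gives no check of the MyoD induction or of the sample labels. Of 196 medians, 1 for each of 28 gene lists in each of 7 comparisons, 12 lay in the outer 5% of random lists, against 9.8 for lists drawn at random. The outer 5% are shared equally between both ends. The rows labelled as 42 sarcomere genes, which encode the contractile apparatus of muscle, had a median log2 difference of -0.10 between iMPCs and MEFs (percentile 4.99, not among the 12), of -0.11 between MEF + MyoD + F/R and MEFs (percentile 2.29) and of -0.07 between C2C12 and MEFs (percentile 1.75). The rows labelled as 13 myogenic regulators went the other way, with medians of 0.29 between iMPCs and MEFs (percentile 98.76) and 0.28 between C2C12 and MEFs (percentile 99.13). Those labelled as excitation-contraction coupling genes had a median of -0.20 between iMPCs and MEFs (percentile 1.91). The other 7 outer medians were as far out, and 6 of them were of lists unrelated to muscle: sex-linked genes (percentiles 0.68, 97.97 and 98.18 in 3 comparisons), cartilage and bone (98.93), macrophages and leukocytes (1.92) and p53 and senescence (98.31). The last was muscle metabolism (98.49, iMPCs against C2C12). The comparisons that follow use only quantities that do not depend on which gene a row is. They still assume that a row holds the signal of 1 gene. This would fail if wrong probes had been summarised into the probe sets, which stays open below.

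**Figure D1:**
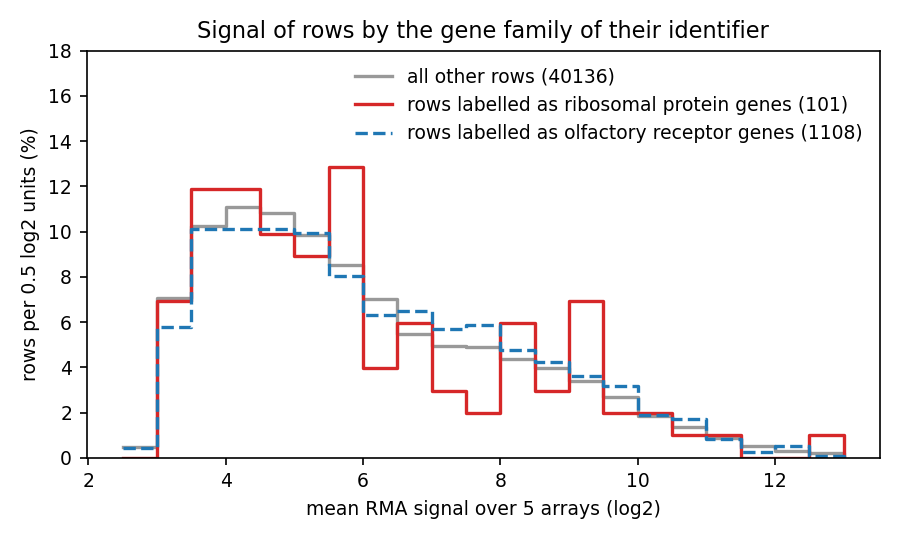
Distribution of the mean RMA signal over the 5 arrays (log2, x axis) as the percentage of rows per 0.5 log2 units (y axis), for rows labelled as ribosomal protein genes (red), as olfactory receptor genes (dashed blue) and for all other rows (grey). The 101 ribosomal protein rows (mean 6.00) and the 1108 olfactory receptor rows (mean 6.16) overlap each other and the rest of the table.

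The MEF + MyoD + F/R cells correlated best with the iMPC line, with a Pearson r of 0.950 across 23314 rows. MEF + MyoD cells correlated best with the unmanipulated MEFs (r = 0.941). The correlation of MEF + MyoD + F/R with MEF + MyoD was 0.928, and with MEFs it was 0.881. The iMPC line and MEFs were the least alike of the 10 pairs by Pearson r (0.876). C2C12 myoblasts correlated with MEFs at 0.925 and with iMPCs at 0.902, with MEF + MyoD at 0.901 and with MEF + MyoD + F/R at 0.881. By Spearman correlation the values were 0.937 for MEF + MyoD + F/R with iMPCs, 0.926 for MEF + MyoD with MEFs and 0.911 for C2C12 with MEFs, and the lowest was 0.864 for MEF + MyoD + F/R with C2C12. The median absolute log2 difference over the same rows ordered the pairs differently: it was smallest between MEFs and MEF + MyoD (0.24, against 0.25 between MEF + MyoD + F/R and iMPCs) and largest between MEF + MyoD + F/R and C2C12 (0.35). These are correlations across rows of single arrays, without a test. The labels give MEF + MyoD as sorted at collection for Thy1, a fibroblast marker. That sort may raise the likeness of this sample to MEFs, which was not tested.

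**Figure D2:**
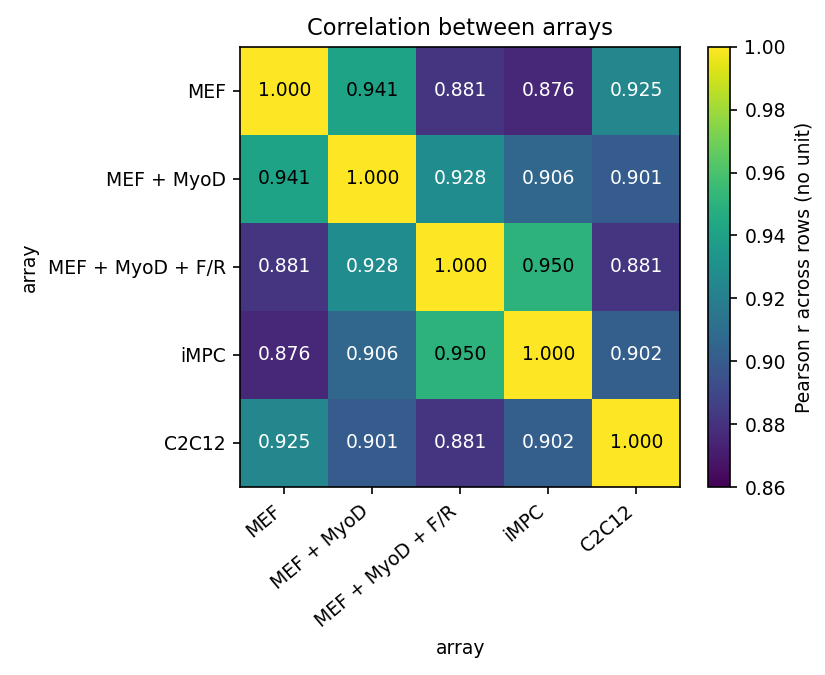
Pearson correlation (colour scale and printed value, no unit) between the log2 signals of each pair of the 5 arrays, across 23314 rows at or above the median in at least 1 array. MEF + MyoD + F/R and iMPC form the pair with the highest Pearson r (0.950), and MEF and iMPC that with the lowest (0.876).

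The first comparison sets fibroblasts after 14 days of MyoD against MEFs. The MEF label names neither a Thy1 sort nor a day, so MyoD cannot be separated from sorting and time in culture. Of the 4 populations set against MEFs here, MEF + MyoD cells differed from them in the fewest rows. In MEF + MyoD cells 1167 rows were at least 2-fold higher than in MEFs and 651 at least 2-fold lower, together 4.40% of the table, and 64.2% of these rows were on the higher side (58.7% with each array centred on its median). At 4-fold there were 292 higher and 86 lower rows, and at 16-fold 34 higher and 5 lower. The higher rows averaged 7.90 in MEF + MyoD and 6.16 in MEFs, with a median difference of 1.42. The lower rows averaged 6.61 in MEF + MyoD and 8.11 in MEFs.

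Adding F/R during MyoD induction went with more rows past 2-fold than MyoD alone against MEFs, 2625 against 1818, but with about as many past 4-fold, 395 against 378, and fewer past 16-fold, 19 against 39. Between MEF + MyoD + F/R and MEF + MyoD cells, 1272 rows were at least 2-fold higher with F/R and 1353 at least 2-fold lower, 6.35% of the table. The share on the higher side was 48.5%, or 50.7% after quantile normalization and 47.1% with each array centred on its median. Most were moderate: the median was 1.46 among the higher rows and -1.32 among the lower rows, and of the rows past 16-fold 15 were higher and 4 lower. The higher rows averaged 8.50 with F/R and 6.87 without. The samples may also differ in the Thy1 sort at collection, which the labels give for MEF + MyoD. The label of the MEF + MyoD + F/R sample breaks off after a comma, so whether that sample was sorted too is unclear, and with 1 array each such a difference could not be separated from F/R. Against MEFs, the MEF + MyoD + F/R cells had 1816 higher and 1522 lower rows, with 124 higher and 10 lower rows past 16-fold. The balance of the 2-fold rows turned with 1 of the scalings: 54.4% were higher as deposited, 53.5% after quantile normalization and 48.9% with each array centred on its median.

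The iMPC line differed most from the fibroblasts. Compared with MEFs, 1794 rows were at least 2-fold higher and 1697 at least 2-fold lower in iMPCs, 8.44% of the table. The largest differences were on the higher side: 624 rows were 4-fold higher against 360 lower, and 167 were 16-fold higher against 21 lower. The largest single differences were 7.38 and -6.53 on the log2 scale.

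The iMPC line also differed widely from C2C12 myoblasts. In iMPCs 1736 rows were at least 2-fold higher than in C2C12 and 1367 at least 2-fold lower, 7.51% of the table. At 16-fold, 100 rows were higher in iMPCs and 5 lower. C2C12 cells compared with MEFs had 1044 higher and 1231 lower rows, with 233 higher and 324 lower past 4-fold and 35 higher and 38 lower past 16-fold. C2C12 is an established line and the labels give no strain for it, whereas the other 4 samples share a strain label, so cell type and origin cannot be separated in these comparisons.

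The fewest differences of the 7 comparisons were between iMPCs and the MEF + MyoD + F/R cells. There 640 rows were at least 2-fold higher and 957 at least 2-fold lower in iMPCs, 3.86% of the table. The share on the higher side, 40.1%, became 49.7% with each array centred on its median and 42.7% after quantile normalization. At 4-fold, 58 rows were higher and 204 lower in iMPCs, so that 22.1% of the 4-fold rows were on the higher side.

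**Figure D3:**
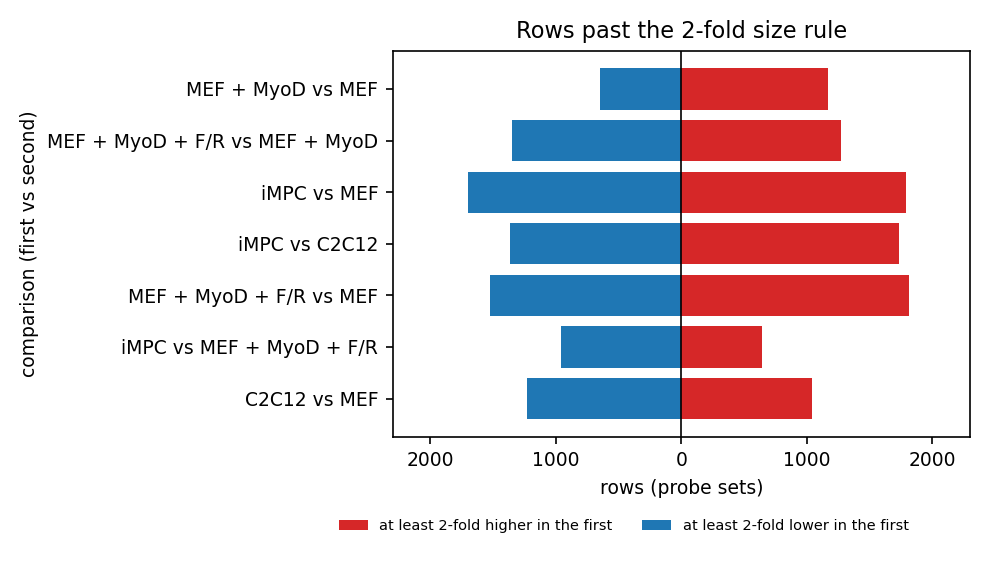
Number of rows (x axis) at least 2-fold higher (red, to the right) or lower (blue, to the left) in the first population of each comparison (y axis), with the higher value at or above its array's median. The iMPC and MEF arrays differ in 1794 and 1697 rows, and the iMPC and MEF + MyoD + F/R arrays in 640 and 957.

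The rows that separate iMPCs from MEFs were used to place the other 3 populations between these end points. The 3 arrays took no part in choosing the rows. The MEF and iMPC arrays did, and they also set the end points. A row in which MEF alone is off draws all 3 arrays towards iMPC. Where iMPC alone is off, they are drawn towards MEF. MEFs stood at least 2-fold below all other populations in 251 rows and above them in 136. For iMPCs these numbers were 91 and 251. In the MEF + MyoD + F/R cells, 71.6% (95% Wilson interval 69.4 to 73.6) of the 1794 rows higher in iMPCs lay nearer the iMPC value than the MEF value, as did 76.8% (74.8 to 78.8) of the 1697 lower rows. In MEF + MyoD cells the shares were 31.0% (28.9 to 33.2) and 26.4% (24.4 to 28.5). In C2C12 they were 31.8% (29.7 to 34.0) and 47.2% (44.8 to 49.6). As a fraction of the log2 distance from MEF to iMPC, the median row stood at 0.75 among the higher and 0.78 among the lower rows in MEF + MyoD + F/R, at 0.31 and 0.24 in MEF + MyoD, and at 0.27 and 0.46 in C2C12. The intervals cover counting of rows only, not variation between cultures. The Thy1 sort at collection may also hold the MEF + MyoD sample nearer to MEFs, which was not tested.

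**Figure D4:**
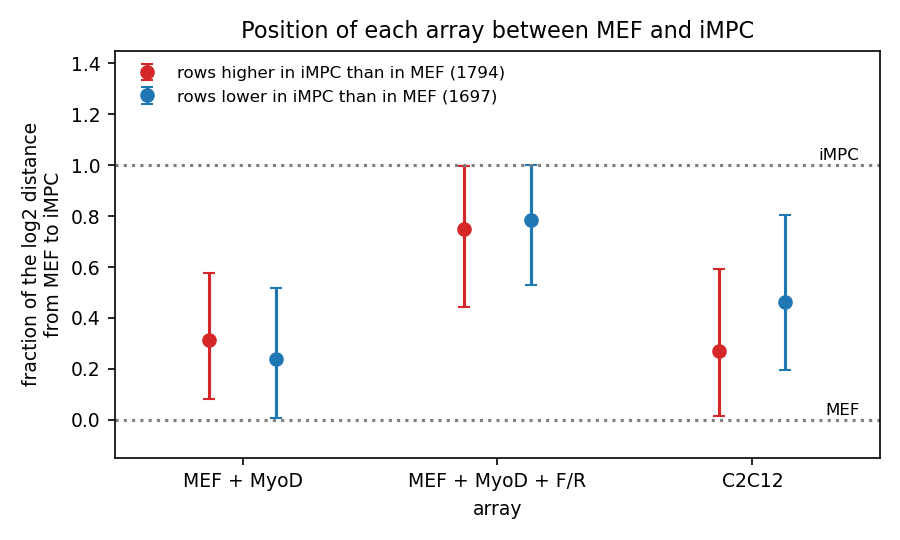
Fraction of the log2 distance from the MEF value (0) to the iMPC value (1) reached in 3 other arrays (x axis), for the 1794 rows higher (red) and the 1697 rows lower (blue) in iMPC than in MEF. Points are medians and bars the 25th to 75th percentile over rows; MEF + MyoD + F/R stands at 0.75 and 0.78, and MEF + MyoD at 0.31 and 0.24.

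The differences that came with F/R were compared with those of the established cells through comparisons that share no array. Of the 1272 rows higher in MEF + MyoD + F/R than in MEF + MyoD, 680 were also higher in iMPCs than in MEFs, where independent lists would share 55.2, and 29 were lower, where independent lists would share 52.2. Of the 1353 rows lower with F/R, 619 were also lower in iMPCs than in MEFs, against 55.5, and 37 were higher, against 58.7. With C2C12 over MEFs, whose lists of 1044 higher and 1231 lower rows are shorter, 336 rows were shared on the higher side, against 32.1, and 139 of the rows higher with F/R were lower in C2C12, against 37.9. On the lower side 313 rows were shared, against 40.3, and 48 of the rows lower with F/R were higher in C2C12, against 34.2. The numbers for independent lists are too low, because they rest on all 41345 rows. Of these, 18031 lay below the median in all 5 arrays and could not pass the size rule. The 48 rows against 34.2 therefore cannot be read as an excess, and the other excesses are smaller than these numbers make them. Rows are not independent, so no p-value is attached to these overlaps.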

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

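The setting that counts identical rows once and the use of all rows for the reported counts were chosen after the data were seen, as was 1 row per symbol for the overlaps. Spearman correlation was a planned measure of similarity, but its use as an alternative setting was chosen then too. No paired analysis was possible because each group has 1 array, and no replicate could be left out. Of the comparisons' counts, those made with another scaling, without the filter, with 8 added to linear values or with identical rows counted once stayed within 1.5 times the reported count, and every other setting moved some, in the order MEF + MyoD against MEF, MEF + MyoD + F/R against MEF + MyoD, iMPC against MEF, iMPC against C2C12, MEF + MyoD + F/R against MEF, iMPC against MEF + MyoD + F/R, and C2C12 against MEF. The planned reduction to 1 row per gene symbol, which keeps fewer rows, gave 993, 1443, 1899, 1739, 1758, 887 and 1260, and the mean of all rows of a symbol 946, 1381, 1813, 1646, 1697, 844 and 1196. A 1.5-fold threshold gave 4392, 5799, 7091, 6685, 6915, 4291 and 5052, and a 4-fold threshold 378, 395, 984, 677, 920, 262 and 557. A filter at the 75th percentile moved 4 counts beyond that range, to 1069 for MEF + MyoD against MEF, 2065 for iMPC against C2C12, 881 for iMPC against MEF + MyoD + F/R and 1457 for C2C12 against MEF. Centring each array on its median took the share of higher rows from 54.4% to 48.9% for MEF + MyoD + F/R against MEF and from 40.1% to 49.7% for iMPC against MEF + MyoD + F/R. Quantile normalization moved these 2 shares less, to 53.5% and 42.7%. The share of higher rows moved by over 10 percentage points only with the 4-fold threshold, to 77.2% for MEF + MyoD and 72.4% for MEF + MyoD + F/R against MEF, 63.4% for iMPC against MEF, 71.9% for iMPC against C2C12 and 22.1% for iMPC against MEF + MyoD + F/R.

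The correlation of MEF + MyoD + F/R with iMPCs exceeded that with MEF + MyoD under the 8 alternatives that can move it (centring cannot), by 0.0072 with all rows and 0.062 with the 75th percentile filter; for C2C12 the excess with MEFs over that with iMPCs was 0.010 and 0.051. The share of rows nearer the iMPC value in MEF + MyoD became 39.1% of the higher rows among 4-fold rows, 28.2% and 29.4% of the higher and lower rows with median centring and 23.4% of the lower rows with the 75th percentile filter. In MEF + MyoD + F/R it was 83.7% and 82.5% among 4-fold rows, 66.6% and 79.3% with centring, 75.8% and 83.0% with the 75th percentile filter, 69.2% of the higher rows with no filter and 79.1% of the lower rows with 8 added. In C2C12 it was 34.1% and 52.2% among 4-fold rows and 35.7% and 43.6% with the 75th percentile filter. Rows shared between the F/R differences and iMPC against MEF, then C2C12 against MEF, each higher then lower, numbered 1370, 1663, 824 and 965 at 1.5-fold and 102, 69, 20 and 39 at 4-fold, and 354, 356, 194 and 178 with 1 row per symbol and 339, 336, 179 and 165 with the mean of a symbol's rows. Gene list medians in the outer 5% of random lists fell to 3 when each list lost its most different member. This pulls a median inwards where that member lies on the median's side, and the random lists lost a member regardless of its difference. Whether this accounts for the fall was not tested. The settings per symbol enter 22180 values in place of 41345, the fold thresholds and the stricter filter change the counts by construction, and for the other moves the cause was not tested. The alternative on identifier endings did not apply to this array, and alternatives for single named genes were not run because no gene could be named.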

Other observations

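Sets of rows in which some populations stood at least 2-fold above all of the rest were counted after the data were seen, and the tests in this part were chosen then too, except quantile normalization, which had been planned as another setting. MEF + MyoD + F/R and iMPCs together stood above the other 3 populations in 382 rows, the most of any pair, whereas iMPCs and C2C12, the 2 established muscle lines, shared 29 such rows. MEF + MyoD + F/R alone stood above all others in 313 rows, C2C12 alone in 277, iMPCs alone in 251, MEF + MyoD alone in 199 and MEFs alone in 136. The 3 populations MEF + MyoD, MEF + MyoD + F/R and iMPCs together stood above both MEFs and C2C12 in 174 rows. In 64 of these the gap was at least 4-fold, with a mean log2 signal of 9.66 in the 3 populations and 5.61 in MEFs and C2C12. MEFs were the single low population in 251 rows and C2C12 in 350.

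The rows did not behave as their identifiers require. A wrong gene annotation over right identifiers is argued against by the background controls, whose identifiers are in the table itself, with a rho with GC count of -0.18 (95% interval -0.55 to 0.25), and a constant shift or reversed order by the largest ribosomal minus olfactory difference over all offsets, 0.963, which 66 of 100 random orders reached. Wrong probes summarised into the right probe sets stay open: equal values in 2 or more arrays were 1.20 times as frequent in miRNA as in protein-coding rows (interval 1.002 to 1.43), which left the matter undecided, and a test then added, the ratio of the SDs of levels of protein-coding and miRNA rows, gave 0.997 (interval 0.947 to 1.06). Both tests rest on assumed bounds and on miRNA probe sets holding fewer probes, which the table does not give. Values and identifiers standing in unrelated orders is a candidate explanation that the ribosomal minus olfactory difference of -0.15 (interval -0.59 to 0.29) leaves standing. For the 8 rows labelled Cwc22 the values argue against unrelated orders. Of these, 4 held identical values, which only 12 of the 41345 rows held, 8 of them outside Cwc22. Unrelated orders would hardly put 4 of 12 such rows under 1 symbol. Cwc22 was singled out after the data were seen, and for the other rows the matter stays open. Over all symbols, 18 pairs of rows sharing a symbol were within 0.15 in all 5 arrays, against at most 16 in 1000 random orders. Of these pairs 10 were among the Cwc22 rows. Without Cwc22 the number was 8, which 80 of the 1000 random orders reached. Equal values in 2 or more arrays were found in 16.5% of protein-coding, 18.5% of long non-coding RNA and 19.8% of miRNA rows. Unrelated orders throughout would give equal shares, whereas the interval of the miRNA ratio, 1.002 to 1.43, lies just above 1. These shares therefore go somewhat against unrelated orders in the whole table, but settle nothing alone. No biological explanation was tested.

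The MEF + MyoD + F/R cells resembled iMPCs more than MEF + MyoD cells, a difference of r of 0.0223, although over all 41345 rows the median absolute difference was 0.199 with iMPCs and 0.195 with MEF + MyoD. Quantile normalization left 0.0222 (resampling interval over rows 0.0197 to 0.0249), but it decides nothing about unequal signal distributions, since the deposited values were already close to each other in distribution and it moved them by a median of only 0.01 to 0.03 log2 units. An artefact shared by these 2 arrays stays open: in the 18031 rows below the median in all arrays MEF + MyoD + F/R lay farther from iMPC than from MEF + MyoD (ratio of median absolute differences 1.18, interval 1.15 to 1.21), but rows near the floor exclude nothing by themselves, and in the 8116 rows at or above the 75th percentile in all arrays it lay closer (0.721, interval 0.697 to 0.752). An effect of the small molecules stays open and untested, as does the Thy1 sort at collection named in the labels for MEF + MyoD and unclear for MEF + MyoD + F/R, and no array batch is given.

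C2C12 cells resembled MEFs more than iMPCs, a difference of r of 0.0227. Quantile normalization left 0.0228 (interval 0.0183 to 0.0272), which decides nothing for the same reason. An array effect may contribute, because C2C12 also lay closer to MEF than to iMPC in the 18031 low rows (ratio 0.813, interval 0.790 to 0.836), but it lay closer in the 8116 bright rows as well (0.781, interval 0.752 to 0.807), and neither value separates an array effect from a difference between the cells. In the 18031 low rows the iMPC array was the one farthest from each of the other 4, with median absolute differences of 0.140 to 0.148. Among the others these differences were 0.113 to 0.136. A difference between the cell lines stays open and untested.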
